A study of Caenorhabditis elegans with 2 samples.

How the data were processed

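The data are ChIP-seq peak lists from 2 biological replicates, per the labels, of whole L4 worms of mixed sex with a GFP-tagged zag-1 transgene. The labels give a fragment size range of 150 to 350 bp and state no read depth. Per the deposited text listings, the authors made 8 peak lists, in the ce11 and ce10 builds, and each replicate list comes from that replicate's alignments and 1 further file, the pooled list from both alignments and the same file, and the optimal IDR list from the pooled and both replicate lists. The aligner, the peak caller, their versions, the IDR threshold and the role of that further file are not given in the sources used here. The control reads that the labels name were not used here.

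Each list has, as deposited by the authors, a signal value per peak in a unit of the authors' caller, which was used only to rank and describe peaks within a list. It also holds, as deposited by the authors, a significance score, the −log10 of a q-value within that list, which served only as an alternative to signal. The lists are of different lengths and signal scales (median signal 14.8 in replicate 1 and 7.95 in replicate 2), so values were not compared between replicates except by rank or correlation. Most regions of a list share 1 width, 340 bp in the IDR list, 356 bp in replicate 1 and 276 bp in replicate 2. Of the IDR peaks, 6 overlap another IDR peak and were counted separately.

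Peaks were placed on the WBcel235 assembly, which is ce11, with Ensembl 115 annotation of 19973 protein-coding genes. All chromosome names matched and no region of the replicate lists ended beyond a chromosome. The ce10 lists were compared as counts and shares, without converting coordinates. Positions are 1-based. A promoter is within 1000 bp of an annotated protein-coding gene start, and a summit was assigned to the nearest such start within 5000 bp. Summits in several annotated features were counted in the order coding exon, 5' UTR, 3' UTR, other exon, intron.

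Replicates were compared at the IDR peaks with the 246 strongest regions of each, and overlap was at least 1 bp. Random placement put each summit on its own chromosome, 100000 times; for overlap, promoters and features this was drawn as binomial counts with the covered share of each chromosome, which equals placing summits independently. For gene lists, placements were matched on chromosome and on signed distance class to the nearest start, with edges at 500, 1000, 2000 and 5000 bp. In the alternatives without distance classes and with lower-ranked regions as background, gene list placements were matched on chromosome alone. Words were counted within 100 bp of a summit and in windows of that size 500 bp to each side, and tested by 100000 random sign flips of the paired differences. Chromosome shares were tested with exact binomial tests. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05, and shares have Wilson 95% intervals. The intervals and p-values are over peaks of 1 combined set, not over worms.

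The 21 gene lists, the rule for named genes and the tests of replicate overlap and correlation, promoter share, gene lists, CAGGTR, hexamers and chromosome shares were fixed before the data were examined. The tests of annotated features and of X against autosomes, with their alternatives, were added afterwards, and the closing section names its own. The rule named zag-1, then the nearest protein-coding gene of each of the 25 strongest IDR peaks, then up to 4 members of each list by signal. Of 606 listed names, 11 had no protein-coding gene of that name in the annotation, and families listed by a shared prefix were taken whole. The alternatives were the ce10 lists, the stronger 50% of the IDR peaks, each replicate's strongest regions in place of the IDR set, other overlaps, distances and windows, lower-ranked regions (2005 in the lower part of the pooled list) as background, and, chosen after seeing the data, the set without X. Chromosome shares were also tested against the share of gene starts in place of length.

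The procedures were tested on simulated sets of 250 summits. In a first series of 20 random sets, the promoter test made a call in 2 sets and the gene list, hexamer and X tests in 0. In a second series of 60, the gene list test made a call in 1 set, the hexamer and promoter tests in 0 and the X test, unadjusted, in 7. For the X test, 5000 further counts were drawn from the binomial distribution that the test assumes, and 4.54% gave a call. A rate near the threshold was thus nearly fixed beforehand. In both series the random summits lay at uniform positions, so they do not show how the hexamer test behaves at promoter-rich summits. With 5 sets in which 10 ribosomal protein genes, a share of promoters, a word and an excess on X were planted, each was called in 5 of 5 and 0 other lists were called. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.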

Results

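ZAG-1 is a zinc-finger homeodomain transcription factor of the ZEB family that acts in neuron differentiation in the nematode Caenorhabditis elegans. Its binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole worms of mixed sex at the L4 larval stage, which carried a GFP-tagged zag-1 transgene. The series has 1 group with 2 biological replicates, so the comparisons are of the replicates with each other and of the peaks with chance. In the ce11 build (WBcel235) the authors listed 11750 regions for replicate 1, 30000 for replicate 2 and 4010 for both replicates pooled, and kept 246 peaks after their reproducibility analysis (irreproducible discovery rate, IDR). The pooled list is labelled as peaks and background put into that analysis. Its −log10 q went down to 0.0167, and those of replicates 1 and 2 to 0.0177 and 0.132. Listed regions outside the IDR set are therefore not all binding sites. These 246 IDR peaks had the 246 highest signal values of the pooled list. The read depth of each library is unknown, because the lists hold no read counts.

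The 25 strongest IDR peaks were led by regions of chromosome X, mostly outside protein-coding genes, and X held 15 of the 25. The strongest, X:11094132-11094339, had a signal value of 296 and lay outside protein-coding genes, 3994 bp downstream of the start of W02H3.3. It was followed on X by X:13700694-13701033, signal 225, with no protein-coding start within 5000 bp, by a region in an intron 3365 bp upstream of the start of cest-16, a carboxylesterase gene, with signal 224, and by regions near ZK899.6 (signal 221), F20B6.9 (220) and nspc-17 (213). A region 4840 bp upstream of xol-1, the master switch gene of sex determination, had signal 189. The autosomal peaks among the 25 included II:5844676-5845015 near ZK1248.17, signal 210, and promoters of rpl-3 (197), tasp-1, a threonine aspartase gene (161), cdc-48.1, a AAA ATPase gene (158), rpl-35 (143) and rpl-15 (118).

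The other named peaks among the 25 lay near T27A8.7 (signal 185), Y41G9A.17 (174), F55G7.5 and F22H10.2 (both 168), gtr-1 (146), F19H6.5 (129) and fbxb-58 (119) on X, and near ins-13, an insulin-like gene (179), sup-26, an RNA-binding protein gene (136), Y111B2A.12 (126) and egg-5 (120) on autosomes. X:5429390-5429729, in a coding exon and with no start within 5000 bp, had signal 118. The signal value is the authors' own score of each peak and has no replicate error.

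No IDR peak lay at zag-1 itself (IV:3855843-3861569, plus strand). The nearest regions of replicate 1 ended at 3838847 and began at 3904862, and those of replicate 2 ended at 3839974 and began at 3880244. Within 15 kb of the start of zag-1 neither replicate had a region, against a median over protein-coding genes of 3 regions in replicate 1 and 9 in replicate 2.

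**Figure D1:**
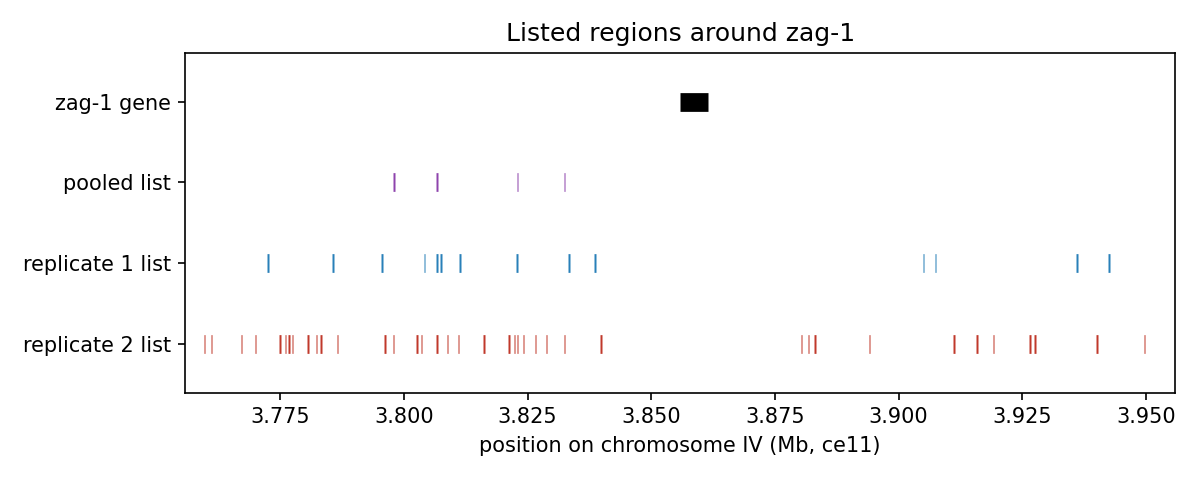
Regions listed in ce11 around zag-1 on chromosome IV (position in Mb), with the gene as a black bar and each region of the pooled list, replicate 1 and replicate 2 as a tick at its place. No list has a region between 3839974 and 3880244.

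The strongest regions of both replicates coincided at the X peaks and at the ribosomal protein gene rpl-3. The X peak near W02H3.3 ranked 1 in replicate 1 and 2 in replicate 2, the peak at cest-16 ranked 10 and 1, and the rpl-3 promoter ranked 12 and 7. All 25 strongest IDR peaks were among the 246 strongest regions of each replicate. Over the whole set, 108 of 246 IDR peaks (43.9%, Wilson 95% interval 37.8 to 50.2) were overlapped by at least 1 bp by a region from the 246 strongest of both replicates. Random placement gave 0.0776% (one-sided permutation p = 1e-05, the smallest that 100000 placements can give). Replicate 1 alone covered 185 peaks (75.2%, interval 69.4 to 80.2) and replicate 2 alone 141 (57.3%, interval 51.1 to 63.3). Of the 246 strongest regions of replicate 1, 109 (44.3%) overlapped one of replicate 2. The IDR set was chosen from these libraries, so its overlap with them is a description of the replicates.

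Across 245 IDR peaks with a region in both replicates, which are not independent replicates, signal values had a Spearman rho of 0.384 and a Pearson r of 0.588 on the log2 scale (permutation p = 1e-05 for each, the smallest possible, 2-sided). Without the 2 peaks farthest from the median in replicate 1, r was 0.564. With the authors' significance score in place of signal, rho was 0.149 (p = 0.0198) and r was -0.0292 (p = 0.644). In the IDR list that score levels off, as the 25 strongest IDR peaks all have its highest value there, 2.39. Its highest values were 2.37 in replicate 1 and 2.46 in replicate 2. These correlations used the scores of the replicate lists, where ties were not counted. Whether levelling off accounts for the weaker agreement by this score is therefore unknown. At rpl-12, which ranked 40 in replicate 1, the best region of replicate 2 ranked 20629, and at nhr-14 the ranks were 146 and 15533.

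**Figure D2:**
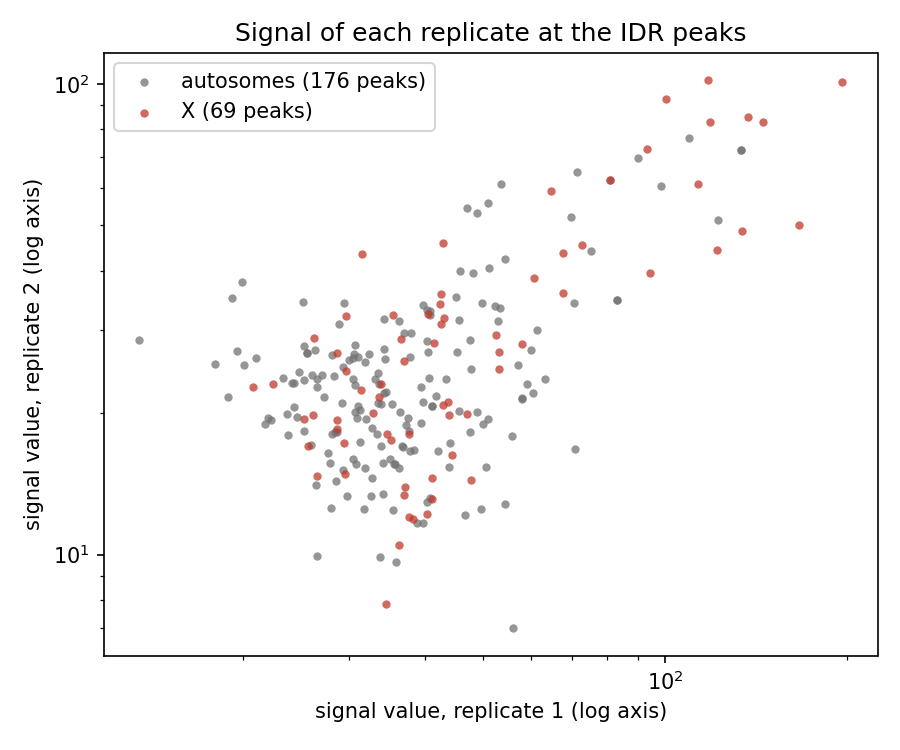
Signal value of the best overlapping region in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) at the 245 IDR peaks with a region in both, 69 on X in red and 176 on autosomes in grey. The peaks with the highest values in both replicates are mostly on X, and the rank correlation over all points is 0.384.

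IDR summits lay in promoters and outside protein-coding genes more often than chance, as at rpl-3 (289 bp upstream of the start), tasp-1 (58 bp), cdc-48.1 (163 bp) and the insulin-like gene ins-39 (648 bp). In all, 141 of 246 summits (57.3%, interval 51.1 to 63.3) lay within 1000 bp of a protein-coding gene start, against 33.4% for random placement on the same chromosomes (2-sided permutation p = 2e-05, the smallest possible). Of these, 122 were upstream, at a median of 282 bp. Among the lower-ranked regions of the pooled list, 37.7% would be within that distance on the same chromosomes (permutation p = 2e-05). Summits on X were within 1000 bp of a start less often than those on autosomes, with 32 of 69 (46.4%) against 109 of 177 (61.6%; Fisher's exact test, 2-sided, p = 0.0325). Chance was also lower on X, at 28.8% against 35.1%, so the share was 1.61 times chance on X and 1.75 times on autosomes, 2 ratios whose difference was not tested. The difference of -15.2 percentage points was -25.7 without replicate 1, -20.9 without replicate 2 and -29.4 in the stronger 50% of peaks.

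By annotation, 181 summits (73.6%, interval 67.7 to 78.7) lay outside protein-coding genes, against 37.2% by chance, while 43 lay in introns (17.5% against 33.8%) and 6 in coding exons (2.44% against 24.1%; permutation test, adjusted p = 4e-05 for each, over 6 classes). The share in coding exons was 6.10% without replicate 1 and 3.25% without replicate 2, both past the threshold. In 5' UTRs there were 9 summits (3.66% against 1.41%, permutation test, adjusted p = 0.0258), a call that was lost in the strongest regions of either replicate alone, at 2.85% in each (adjusted p = 0.177 without replicate 1 and 0.143 without replicate 2) and in the stronger 50% of peaks (1.63%, adjusted p = 1). The share in 3' UTRs, 2.44% against 3.40%, did not pass (permutation test, adjusted p = 0.567) except without replicate 2, at 0.813% (adjusted p = 0.0285), nor did that in other exons, at 0.407% (adjusted p = 0.567).

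Chromosome X held 69 of the 246 summits (28.0%, interval 22.8 to 34.0) against 17.7% of the genome's length (exact binomial test, 2-sided, adjusted p = 0.000378 over 7 tests). V held 34 (13.8% against 20.9%, exact binomial test, adjusted p = 0.0206), IV 29 (11.8% against 17.4%, adjusted p = 0.0430) and II 25 (10.2% against 15.2%, adjusted p = 0.0459), all below their length. I (46 summits, 18.7% against 15.03%) and III (43, 17.5% against 13.7%) did not differ past the threshold (exact binomial test, adjusted p = 0.109 for each). The arms, the outer parts that make up 66.7% of each chromosome, held 150 summits (61.0%, exact binomial test, adjusted p = 0.0946). IV was no longer past the threshold in the strongest regions of replicate 2 (14.2%, adjusted p = 0.207) or of replicate 1 (12.6%, exact binomial test, adjusted p = 0.0512), II was no longer past it in the stronger 50% of peaks (11.4%, adjusted p = 0.365), I passed in the strongest regions of replicate 1 (21.5%, adjusted p = 0.0125), and the arms fell below their length in each (58.1%, adjusted p = 0.0128, without replicate 1, and 57.3%, adjusted p = 0.00535, without replicate 2).

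**Figure D3:**
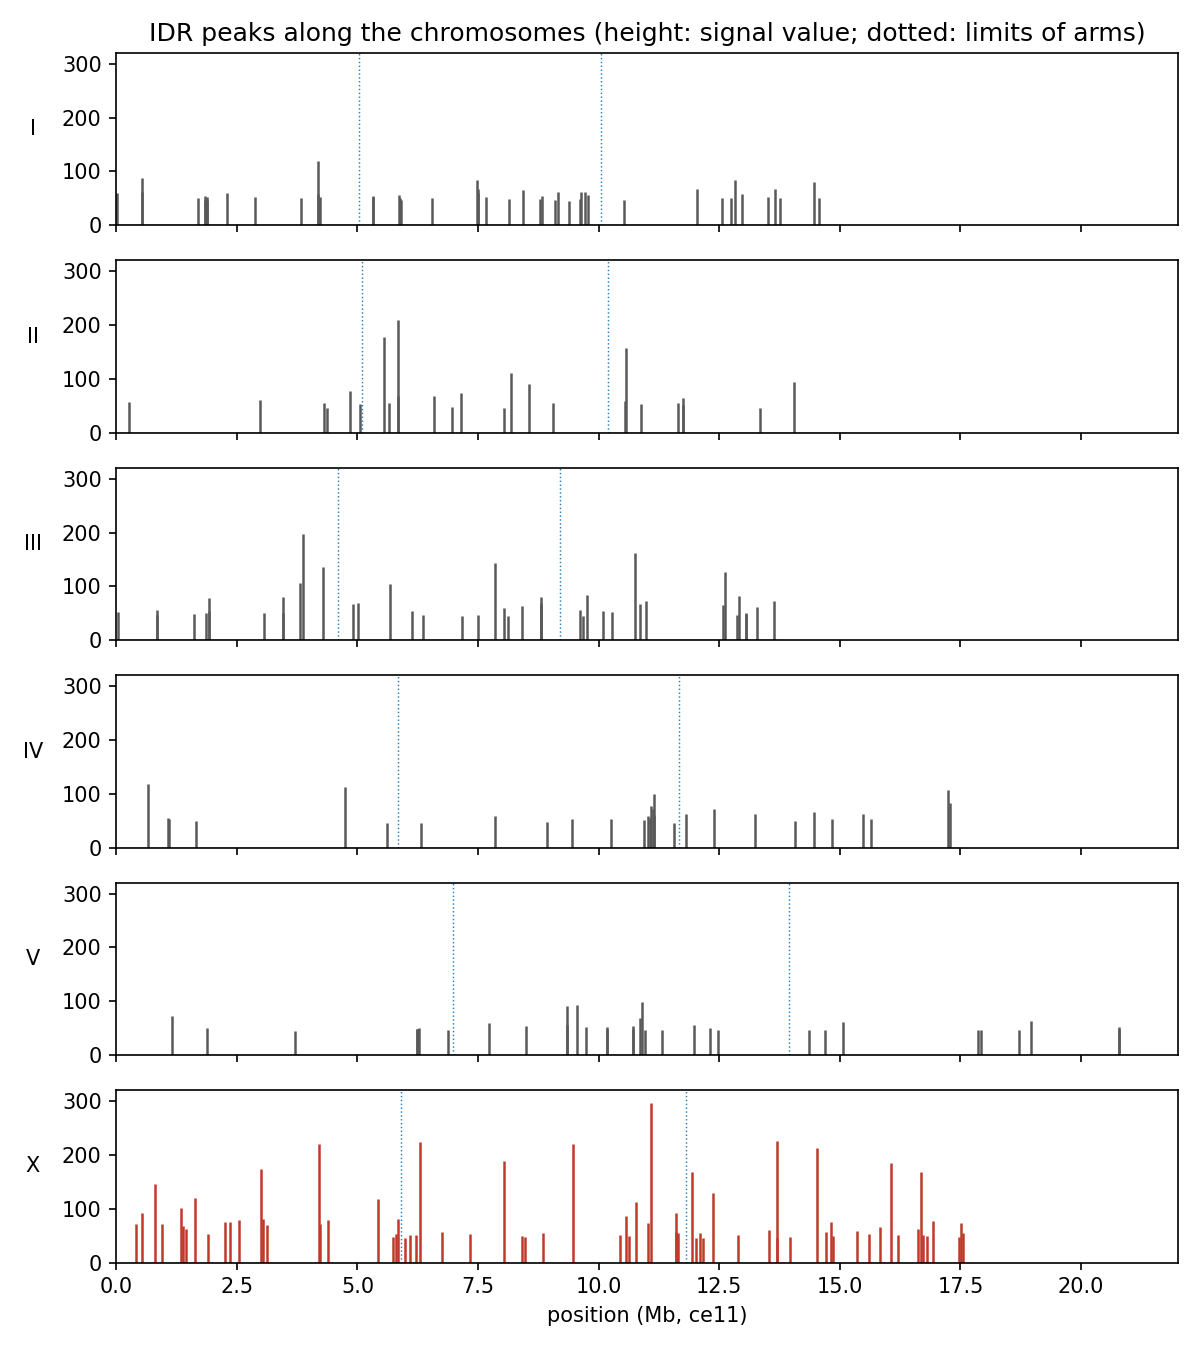
The 246 IDR peaks along chromosomes I to V and X (position in Mb, ce11), each line's height its signal value, with X in red and dotted lines at the limits of the arms. X holds 69 peaks and 15 of the 25 strongest.

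Ribosomal protein genes were the group with the clearest excess near IDR peaks. Of 82 members, 9 were the nearest start to a summit within 5000 bp, against 0.677 for placements matched on chromosome and distance to a start, which is 13.3-fold (2-sided permutation p = 2e-05, the smallest possible; adjusted p = 0.00042 over 21 lists). The strongest were rpl-3 (signal 197), rpl-35 (143), rpl-15 (118) and rpl-11.2 (75.6), each with its summit upstream, at 289, 438, 355 and 393 bp. The others, named after their values were seen, were rps-23 (71.0), rpl-12 (63.1), rps-15 (54.3), ubl-1 (49.8) and rps-28 (48.7).

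The neuronal lists did not pass. Pan-neuronal genes had 3 of 30 members near a summit, unc-64, which encodes syntaxin (signal 62.1), unc-108, a Rab GTPase gene (50.1), and egl-3, a proprotein convertase gene (48.9), against 0.50 by chance (permutation test, adjusted p = 0.185). The monoamine and glutamate list had cat-2, the tyrosine hydroxylase gene (56.9), against 0.197 (permutation test, adjusted p = 1), and the neuropeptide list ins-13 (179) and ins-39 (101) against 2.23 (adjusted p = 1). Touch receptor (chance 0.332), GABA (0.185), cholinergic (0.309) and axon guidance (0.917) genes had 0 members near a summit (permutation test, adjusted p = 1 for each). With chance counts this low a count of 0 cannot show a depletion, so these lists give no evidence against neuronal targets.

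Among regulators, bHLH genes had 4 of 41 members, mdl-1 (signal 56.9), hlh-11 (56.7), hlh-29 (55.4) and hif-1, the hypoxia factor (48.8), against 0.633 (permutation p = 0.00732, adjusted p = 0.0769). Nuclear hormone receptor genes had nhr-1 (74.3), nhr-88 (60.9), daf-12 (49.0) and nhr-14 (47.7) against 2.77, homeobox genes had ceh-38 (48.1) against 1.71, and the heterochronic and moulting list had daf-12 against 0.325 (permutation test, adjusted p = 1 for each). Signalling genes had sma-9 (112), mig-5, a Dishevelled gene (112), and daf-14, a Smad gene (52.8), against 0.819, and stress response genes had hsp-1 (82.8), zip-2 (55.4) and hsp-3 (50.8) against 0.763 (permutation test, adjusted p = 0.402 for each). Of the tissue and housekeeping lists, collagen and cuticle genes had col-94 (72.4) and col-181 (55.4) against 2.09, germline genes cgh-1 (46.9) against 0.481, and histone genes his-37 (93.4) against 0.325 (permutation test, adjusted p = 1 for each). Body wall muscle (0.821), pharynx (0.331), intestine (0.613) and hypodermis (0.465) genes had 0 members (permutation test, adjusted p = 1 for each). In the permutation test with lower-ranked regions as the background, bHLH genes (adjusted p = 0.00504) and stress response genes (adjusted p = 0.0143) also passed. That test was not matched on distance to a start, and lower-ranked regions lie near starts less often. These 2 calls may therefore come from distance alone.

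**Figure D4:**
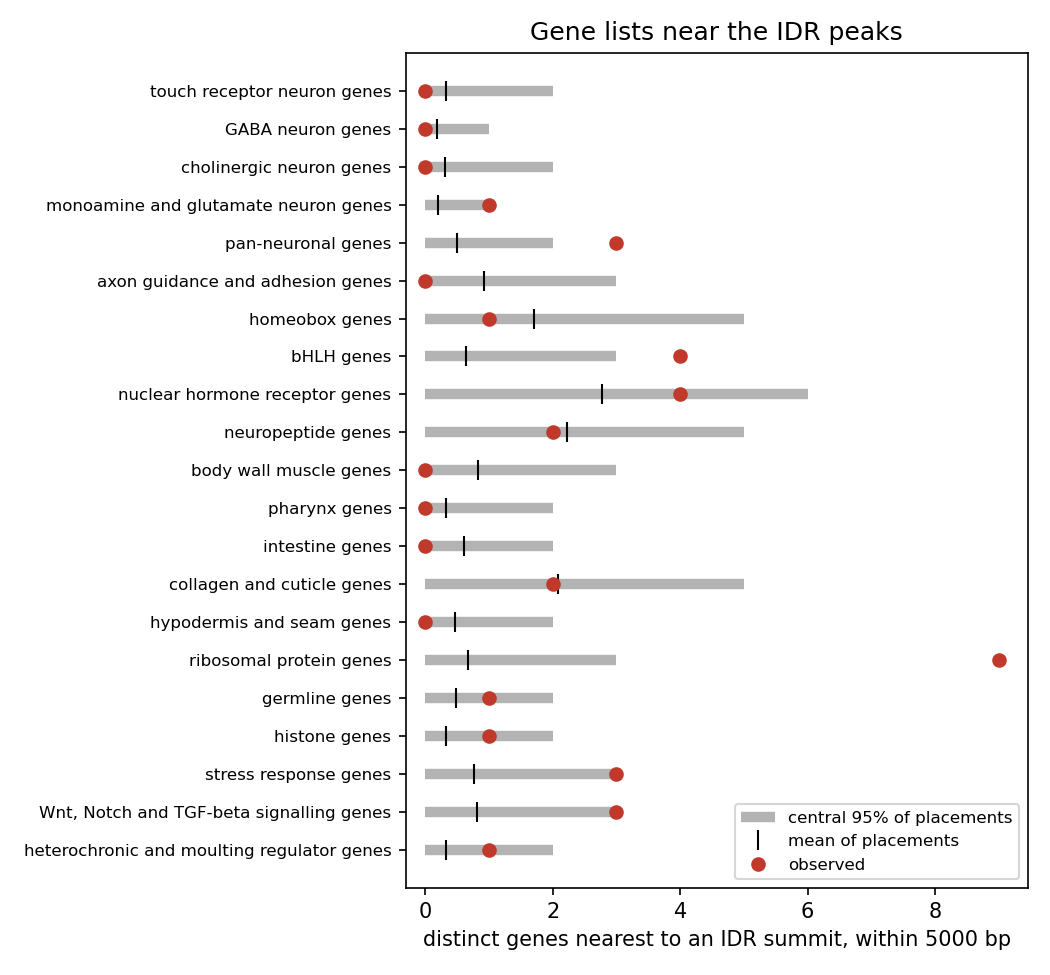
Number of distinct genes of each of 21 lists nearest to an IDR summit within 5000 bp (red), with the mean (black tick) and the central 95% (grey) of 100000 placements matched on chromosome and distance to a start. Ribosomal protein genes, at 9 against 0.677, are the list past the threshold after adjustment.

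The word CAGGTR (CAGGTA or CAGGTG on either strand), bound by ZEB-type zinc fingers, was not higher at IDR summits, and 0 of the 9 ribosomal protein gene peaks held it. Within 100 bp of the summit it occurred 0.0772 times per peak, against 0.122 in windows 500 bp away, a difference of -0.0447 with a standard error of 0.0236 over 246 peaks (paired sign-flip permutation test, 2-sided, p = 0.0708). It was in 19 summit windows (7.72%, interval 5.0 to 11.7), against 8.98% of lower-ranked regions (Fisher's exact test, p = 0.634). The difference was past the threshold of the permutation test, in the same direction, in the strongest regions of either replicate, at -0.0569 (p = 0.0122) without replicate 1 and -0.0772 (p = 0.00131) without replicate 2.

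Other words were higher at the summits. GAGAGA occurred 1.37 times per summit window against 0.173 in the flanks, and was in 49.6% of summit windows against 14.7% of those of lower-ranked regions. CACACA occurred 0.760 times against 0.159. CGTCTC was in 42.3% of summit windows against 8.13% of lower-ranked ones, and ACGCAG in 33.7% against 6.33%. Each of these hexamers had an adjusted p of 0.000168 against the flanks. Of all hexamers, merged with their reverse complements, 251 were higher at the summits and 307 lower (sign-flip permutation test, adjusted over the hexamers). Without replicate 1, 116 were higher and 85 lower. Neither the flanks nor the lower-ranked regions were matched to the summits for annotated feature. Outside protein-coding genes lay 73.6% of IDR summits and 40.9% of lower-ranked ones. General differences in sequence between promoters and genes were therefore not separated from words particular to these peaks.

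**Figure D5:**
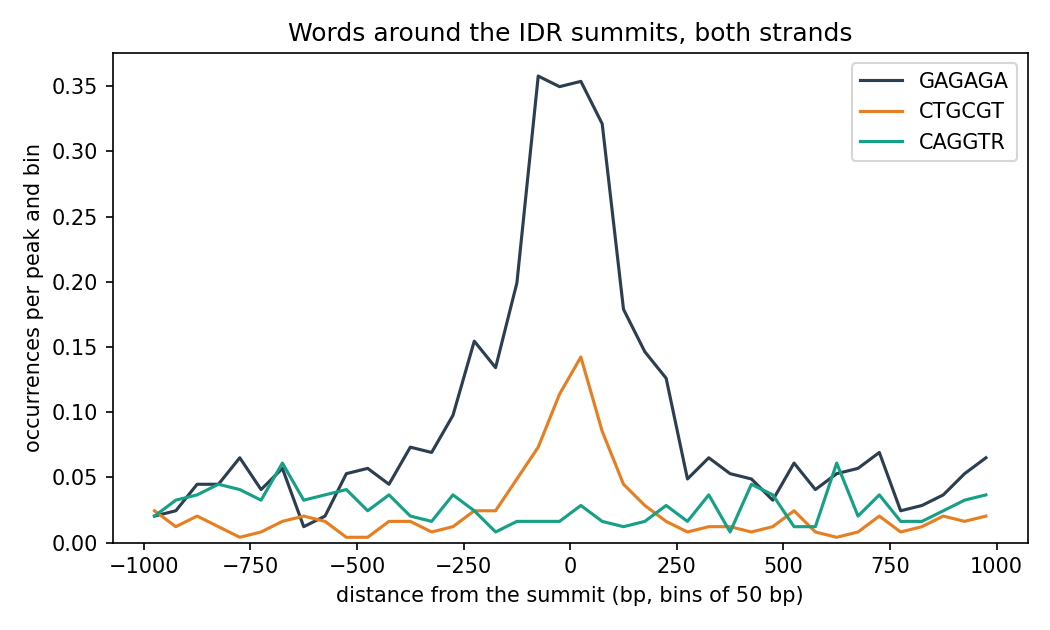
Occurrences per peak of GAGAGA, CTGCGT (the other strand of ACGCAG) and CAGGTR, both strands counted, in bins of 50 bp to 1000 bp on each side of the 246 IDR summits. GAGAGA and CTGCGT rise at the summit, and CAGGTR does not.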

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

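No paired analysis was possible because there is only 1 group. The set without X, and every setting of the annotated features and of X against autosomes, were chosen after seeing the data, and the other alternatives before. Of the main results, 31 alternative values kept their direction and their side of the threshold. These include the ce10 lists (217 IDR peaks), every setting of the replicate overlap, the rank correlation, the promoter share and the X share. Removing peaks within 50 kb of zag-1 removed 0 peaks, so that setting tests nothing and is left out of the counts. The causes of the changes below were not tested. The CAGGTR difference went past the threshold in the same direction with the stronger 50% of peaks (-0.0732), without X (-0.0763) and with windows of 200 bp (-0.120), and ranged from -0.0772 to -0.0569 with 1 replicate left out; it did not with 50 bp windows (-0.0102) or against control words of the same composition (-0.0592; exact rank among the 21301 pairs of such words, p = 0.204). Hexamers higher at the summits numbered 112 with the stronger 50% of peaks, where fewer peaks were tested, 159 without X, also with fewer peaks, 406 against lower-ranked regions, and 116 to 232 with 1 replicate left out. Against lower-ranked regions, in a test not matched on distance to a start, 3 gene lists passed, not 1. The arms held 57.3% to 58.1% of summits with 1 replicate left out, and passed against length. With the share of gene starts expected, tried on the IDR set only, they did not pass.

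Among other results, 178 values kept direction and call, 4 gained a call (bHLH and stress response lists, 3' UTRs and chromosome I) and 8 lost one (5' UTRs and chromosomes II and IV), and 25 changed direction, none of them past the threshold in either setting. With the stronger 50% of peaks these were neuropeptide (2 genes), germline (0) and heterochronic (0) lists, other exons (0%) and chromosome I (14.6%). With 1 replicate left out they were axon guidance (1), collagen (4), germline (0), heterochronic (0), body wall muscle (1) and hypodermis (1) lists and, without replicate 2, other exons (0%; without replicate 1 they were at the main value of 0.407%). Without X they were homeobox (1), nuclear hormone receptor (1) and heterochronic (0) lists. Against lower-ranked regions they were neuropeptide (2) and collagen (2) lists, and without distance classes collagen (2). Within 2000 bp they were monoamine (0), neuropeptide (2) and collagen (2) lists, and with every start within 2000 bp monoamine (0), neuropeptide (3) and hypodermis (1) lists. Depth is unknown, so weak sites in either library cannot be ruled out.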

Other observations

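The tests of short RNA genes and of the share of genes with no region nearby were chosen after those results were seen; so were the deciding test on ribosomal protein genes in each replicate and the limit on the share of their peaks with CAGGTR. Starts of short RNA genes were over-represented at IDR summits. Within 300 bp of a tRNA or snRNA gene start lay 17 of 246 summits (6.91%, interval 4.36 to 10.8), against 0.463% by random placement (permutation p = 2e-05, the smallest possible, 2-sided) and 1.30% of lower-ranked regions (Fisher's exact test, p = 8.13e-07). tRNA genes accounted for 9 and snRNA genes for 8, and the snRNA peaks include sls-2.1 (signal 210), sls-2.2 (179) and sls-2.4 (120), genes of SL2 spliced leader RNA. Those peaks had been assigned to ZK1248.17, ins-13 and egg-5, because the assignment used protein-coding genes. Likewise the peak assigned to col-94, 1775 bp from its start, lay 31 bp from the start of the snRNA gene R07E5.16. snoRNA genes had 8 summits (3.25% against 0.198%, permutation test, adjusted p = 2.5e-05) and miRNA genes 1 (adjusted p = 0.609). These counts are the ones that drew attention to the short RNA genes, and no separate test of a preference for them was made; overlapping peaks at sls-2.1 and sls-2.4 were counted separately.

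Of the 251 hexamers higher at IDR summits, 5 make up the word CTGCGTCTCT, which was read from those same peaks and was present in 31 of 246 summit windows (12.6%). The test therefore used other regions, the 1748 of the upper part of the pooled list that overlap no IDR peak. There the word was in 2.92% of summit windows (interval 2.23 to 3.82) against 0.572% of flanks (sign-flip permutation p = 1e-05, the smallest possible). The word may join these 5 hexamers at listed regions, which are not all binding sites. It was in 1 of the 15 X peaks among the strongest 25 and in 0 of the 9 ribosomal protein gene peaks.

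The strongest peaks on X lie far from gene starts: 2 of 15 X peaks among the strongest 25 are within 1000 bp of one, against 7 of 10 autosomal ones. Repeated sequence is argued against, since the median share of 36-base words found more than once in the genome was 0%. For a signal of 1 replicate alone, 15 of 15 were among the 246 strongest regions of both, as were all of the strongest 25. They are the strongest peaks of a set selected for reproducibility. This outcome was thus nearly fixed beforehand, and it describes these peaks without testing that explanation. A match with at most 2 mismatches to TCGCGCAGGGAG, a consensus of the element that recruits the dosage compensation complex to X (recalled and not checked against a source, and chosen after these peaks had been seen), lay within 100 bp of 12 of these 15 summits, and 200 shuffled motifs reached at most 3. It was in 2 of 54 other X peaks and 5 of 177 autosomal ones. As a hypothesis, the 12 peaks with a match may be loading sites of the complex. Why they would appear in a ZAG-1 experiment is open, and an artefact shared by ChIP experiments at open chromatin was not tested, since no ChIP of another factor was used here.

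No region was listed around zag-1 in a stretch of 40269 bp shared by both replicates. Few genes share such a gap, as 78 of 19973 protein-coding genes (0.391%) have no region of either replicate within 15 kb. This test was chosen after the gap was seen, so zag-1 had to be among them, and no chance model was used. Among gaps between neighbouring regions, that at zag-1 ranked 21 of 11744 by length in replicate 1 and 9 of 29994 in replicate 2. Repeated sequence is argued against, since 0.120% of 36-base words around zag-1 occur more than once. Absence of binding as the sole explanation was not tested and is not decided. Lack of an IDR peak does not usually come with such a gap, since the lists hold weak regions near nearly all genes. Most of those genes have no IDR peak nearby. The −log10 q of the listed regions went down to 0.0177 in replicate 1 and 0.132 in replicate 2. Extra copies of zag-1 and its surroundings on the transgene could raise a control from the same strain as much as the ChIP. That cannot be tested without the control reads, not used here. No biological explanation was tested.

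Ribosomal protein gene promoters are over-represented among IDR peaks and neuronal lists did not pass. Binding through CAGGTR within 100 bp of the summit at most of these peaks is argued against, since 0 of 9 held the word. The upper limit was 29.9%, by a rule chosen after that count was seen. At a smaller part of them such binding stays open. The 9 peaks cannot be set apart from their flanks, where 5 of 18 windows held the word (Fisher's exact test, p = 0.136). Binding farther from the summit or through other words was not tested. For a signal of 1 replicate alone, the bound set beforehand was met: 4 of 9 peaks, under 50%, are among the 246 strongest regions of both replicates. A test chosen afterwards argues against that explanation for the excess of the list as a whole. The list passed in the strongest regions of each replicate taken alone, with 8 genes without replicate 1 (permutation test, adjusted p = 0.00042) and 6 without replicate 2 (adjusted p = 0.0021), which an excess from 1 library forbids. It used other sets of regions than the 9 peaks. Single peaks among the 9 may still rest mainly on 1 library, as at rpl-12, which ranked 40 and 20629. High transcription of these genes as a source of ChIP background stays open and was not tested.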
